A study of Mus musculus with 33 samples.

How the data were processed

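RNA was measured by polyA RNA-seq in 12 libraries of mouse embryonic stem (ES) cells. The cells came from a CAST/Ei × 129/Sv/Jae cross and were labelled WT or RepB, a genotype named after Repeat B of the Xist RNA. The labels do not describe the edit or name the allele that carries it. Per the labels the cells were grown on irradiated feeder fibroblasts with LIF, freed of feeders, kept as embryoid bodies in suspension and then plated on gelatin. Each genotype had 1 library at each of days 0, 5, 6, 7, 8 and 10, so there were no replicate cultures. The other 21 samples, 18 ChIP and input samples of ES cells and 3 of fibroblasts, were not analysed here.

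The deposited table gave counts per gene, without normalization, for 24391 genes, 1063 of them X-linked. The authors gave total counts and, in separate columns, counts of reads assigned to alleles named cas and mus, read here as CAST/Ei and 129/Sv/Jae. The processing notes of the labels list mm9, Novoalign, TopHat, SAMtools, bedtools and featureCounts without versions or roles. The other unit among the deposited columns is the summed exon length of each gene in bases. The library kit was directional, but the strand setting of the counting was not stated, so counts of genes that overlap on opposite strands, such as Xist and Tsix, are uncertain. Genes that share sequence with close relatives, such as the globins, H2-Bl and Hist1h2ao, are uncertain for the same kind of reason. The table held 6 further count columns for a day with no matching RNA sample, and these were not used. In 27 rows the gene name had been turned into a date, and 2 names were duplicated. Total counts were never below the sum of cas and mus counts (0 rows).

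Library totals ranged from 3594551 counts (RepB day 8) to 17773138 counts (WT day 5). Allelic counts were 25.5% to 26.7% of the total. A gene with no count in a library can be bounded only by 3 counts, which is 0.169 to 0.835 CPM (the count scaled to a common library total) across the libraries. Intervals for shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since the labels name no molecular identifiers.

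Counts were analysed in R 4.3.3 with edgeR 4.0.16, using trimmed-mean (TMM) normalization, filterByExpr on genotype-by-stage groups and the quasi-likelihood F test. P values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05, and every adjusted p below comes from these fits unless another test is named. A single fit of the 12 libraries had day as a factor and a genotype effect at day 0 and over days 5 to 10, which left 4 residual degrees of freedom. It tested RepB against WT over days 5 to 10, the same difference less that at day 0, and days 5 to 10 against day 0. A fit of the 10 libraries of days 5 to 10 tested the slope per day, and another the difference of slopes between genotypes. In the tests of RepB against WT the 5 differentiating days served as blocks. Each p there measures how steady a difference was over the days of 1 time course of 1 line per genotype. The test against day 0 used the same fit, so its spread was that of the RepB/WT difference over days, not that between days. The slope fits had no day blocks, and their spread was that around straight lines. No p says anything about other cultures or lines. The common dispersion was 0.015, a biological coefficient of variation of 12.2%.

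Fixed gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and fry results were kept. The lists covered the X-inactivation centre, escape genes, genes tied to the presence of an X pair in ES cells, Y-linked genes, naive pluripotency, formative epiblast, neural ectoderm, mesoderm, endoderm, cardiac muscle, blood and endothelium, trophoblast, fibroblast and feeder cells, Polycomb subunits, Xist partners, Hox genes, imprinted genes, ribosomal proteins, p53 targets and the cell cycle. The named genes were up to 8 with the largest rise and 8 with the largest fall among those past the threshold, with an average log2 CPM of at least 2, a named symbol and, for RepB against WT, the same sign on each of the 5 days. Xist, Tsix, Jpx, Ftx and Rlim were always named. Up to 4 members of each list were named by highest mean CPM, besides any member past the threshold. These comparisons, lists, rules and most alternatives were fixed before the data were examined. Further genes, and the choice of autosomal background genes described next, were chosen after values were seen.

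Allelic shares used genes with a mean of at least 20 allelic counts, and at least 10 in a library for its share. The background was autosomal genes with a cas share of 25% to 75% at day 0. Allele-by-genotype effects per gene were tested with edgeR quasi-likelihood on cas and mus counts, with 4 residual degrees of freedom. X-linked output was the median log2 RepB/WT of X-linked genes less the autosomal median, with a pseudocount of 0.5 CPM, for genes with a mean CPM of at least 1. Differences over the 5 days were tested by exact two-sided sign-flip tests, whose smallest possible p is 0.0625. The X-linked median was also set against 10000 random autosomal lists matched on mean expression. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

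On simulated counts with the same design, the RepB against WT test called 31 of 67 genes with a 1.5-fold change, 62 of 67 with a 2-fold change and 66 of 66 with a 4-fold change, with 10 false calls. The test of the difference from day 0 called 5 of 67 genes at 2-fold and 62 of 66 at 4-fold. The difference of slopes was called for 1 of 67 genes at a 2-fold difference reached between days 5 and 10 and for 38 of 66 at 4-fold. The allele test called 73 of 100 genes at a log2 odds ratio of 1 and 97 of 100 at 2. In the gene simulations the changed genes were drawn from those with higher counts, and all genes had the same dispersion, set above the common dispersion of the data. The slope simulation used flat courses over days, and the allele simulation used balanced alleles. These rates therefore need not hold for all genes.

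Alternatives were size factors by relative log expression, TMM from autosomal genes, no low-count filter, DESeq2 1.42.0, limma-voom, other forms of the design, a higher expression or allelic count minimum, leaving out the escape and X-inactivation centre lists, means or pooled counts in place of medians, no autosomal reference, and leaving out each day in turn. Thinning the deeper library of each day to the total of its partner, and limiting X-linked genes to those with a cas share of 25% to 75% at day 0, were added after seeing the data, as were all alternatives for the allele test of days 5 to 10 less day 0.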

Results

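Gene expression was followed in WT and RepB ES cells at day 0, before differentiation, and at days 5, 6, 7, 8 and 10 of differentiation, with 1 library per genotype and day. The cells came from a cross of CAST/Ei with 129/Sv/Jae mice, so that reads over strain variants could be assigned to the CAST/Ei (cas) or the 129/Sv/Jae (mus) allele. Xist is the noncoding RNA that coats and silences 1 X chromosome in female cells, and RepB is named after its Repeat B. In order of day, the WT libraries held 16888957, 17773138, 14409430, 11238856, 7763633 and 10200004 counts. The RepB libraries held 15231930, 5297648, 6977752, 4428785, 3594551 and 3745822 counts. WT libraries were therefore 2.07 to 3.35 times deeper than RepB libraries over days 5 to 10, and 1.11 times deeper at day 0. Libraries were ordered by day along the main axis of variation, which held 55.1% of the variance, and same-day WT and RepB libraries correlated across genes with r of 0.971 (day 8) to 0.99 (day 0). Genes are not independent replicates in these correlations. Means over days are given with the SD over the 5 differentiating days.

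Xist (X chromosome, mm9, first listed exon 100655712 to 100663375) was abundant in both lines throughout differentiation. In WT it stood at 371 CPM at day 0 and at 1252, 1298, 1386, 820 and 1021 CPM at days 5, 6, 7, 8 and 10. In RepB it stood at 107 CPM at day 0 and at 1452, 1171, 1642, 1396 and 1277 CPM later. Over days 5 to 10 the log2 RepB/WT ratio was 0.28 ± 0.33 (SD, n = 5), higher in RepB on 4 of 5 days, which did not pass an exact sign-flip test (p = 0.125) or the gene test (adjusted p = 0.259). At day 0 the ratio was -1.79, a WT level 3.46 times that of RepB, from 1 library each. These counts cover all exons of the gene and so do not check the edit of Repeat B. Xist reads were mostly of the mus allele in both lines. The cas allele gave 1.9% (95% interval 1.6 to 2.3) to 4.3% (3.4 to 5.4) of allelic Xist counts in WT over days 5 to 10. In RepB it gave 18.6% (17.0 to 20.3) at day 5, 17.1% at day 6, 13.6% at day 7, 12.3% at day 8 and 6.4% (5.1 to 7.9) at day 10.

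The Xist cas share over days 5 to 10 was 2.9% ± 0.9 in WT and 13.6% ± 4.8 in RepB (SD, n = 5), higher in RepB on 5 of 5 days (exact sign-flip p = 0.0625, the smallest possible). The allele test gave a log2 odds ratio of 2.50 ± 0.18 (SE, adjusted p = 8.9e-10). At day 0 the shares were 3.2% (2.4 to 4.1) and 4.5% (2.8 to 6.9), with overlapping intervals. Tsix, the antisense partner of Xist, was lower in RepB over days 5 to 10 by the gene test, at 17.3 CPM in WT and 10.3 CPM in RepB (log2 -0.74 ± 0.12, adjusted p = 0.00838). This value is uncertain, since the strand setting of the counting was not stated, and leaving out day 7 ended the call. Jpx (log2 -0.06, adjusted p = 0.948), Ftx (0.18, 0.466) and Rlim (0.12, 0.507) did not pass the test.

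**Figure D1:**
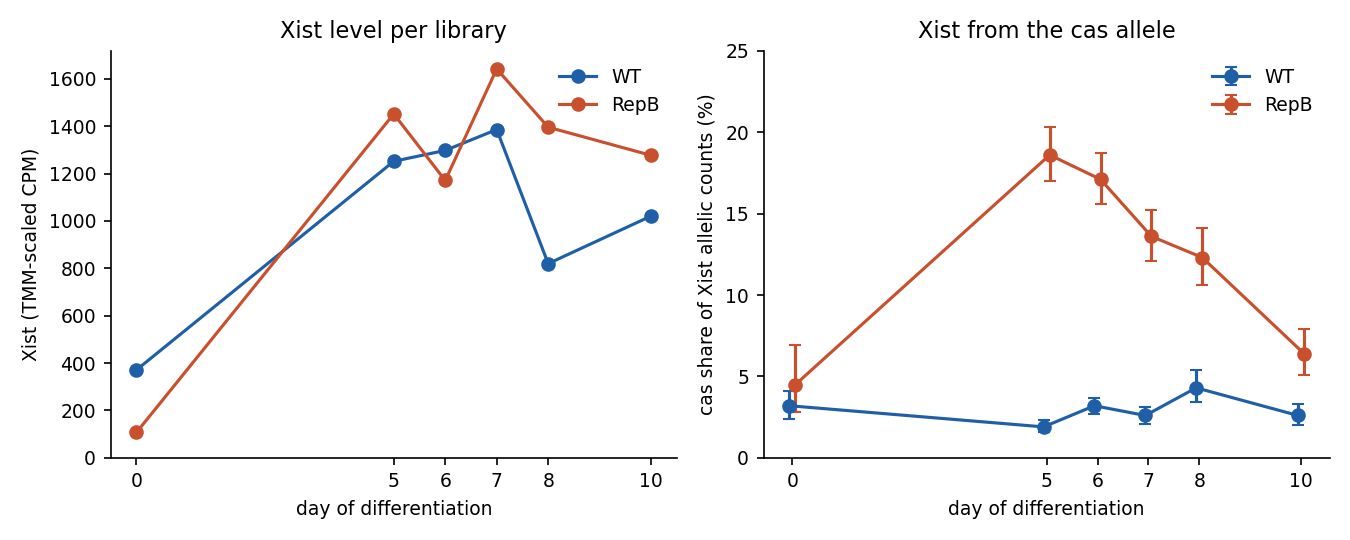
Xist level in CPM and the cas share of allelic Xist counts in percent, by day, for WT and RepB, with 1 library per point and exact 95% intervals on the shares. Over days 5 to 10 the RepB cas share lay between 6.4% and 18.6%, and the WT share between 1.9% and 4.3%.

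The series compares WT with RepB during differentiation to follow the establishment of X-inactivation, and the allelic counts read it on each X chromosome. In WT the X-linked genes moved from balanced expression toward the cas allele. The median cas share over informative X-linked genes was 51.0% at day 0 and 78.7%, 86.2%, 90.9%, 92.3% and 93.4% at days 5, 6, 7, 8 and 10. In RepB it was 51.6% at day 0 and 62.9%, 66.7%, 70.5%, 75% and 73.0% later. The mean over days 5 to 10 was 88.3% ± 6.0 in WT and 69.6% ± 4.9 in RepB (SD, n = 5). The share pooled over X-linked genes at day 10 was 84.2% (95% interval 83.8 to 84.4) in WT and 65.9% (65.3 to 66.4) in RepB.

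RepB lay below WT on 5 of 5 days, by 15.8 points at day 5 to 20.5 points at day 7 in size, with a mean difference of -18.7 points ± 2.1 (SD, n = 5; exact two-sided sign-flip p = 0.0625, the smallest this design allows). The background of 3203 autosomal genes with both alleles at day 0 differed by 0.18 points ± 0.37 (exact p = 0.375), and X-linked genes differed by 0.7 points at day 0. Most background genes lay on chromosomes 2, 5, 6, 7, 8, 9, 11 and 13. On the remaining autosomes only 1.2% (chromosome 19) to 4.6% (chromosomes 14 and 15) of genes qualified. The background is therefore not genome-wide, and its choice by a day 0 share of 25% to 75% centres its day 0 median. At day 10, 68.2% of X-linked genes had a cas share of at least 90% in WT and 15.2% in RepB.

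**Figure D2:**
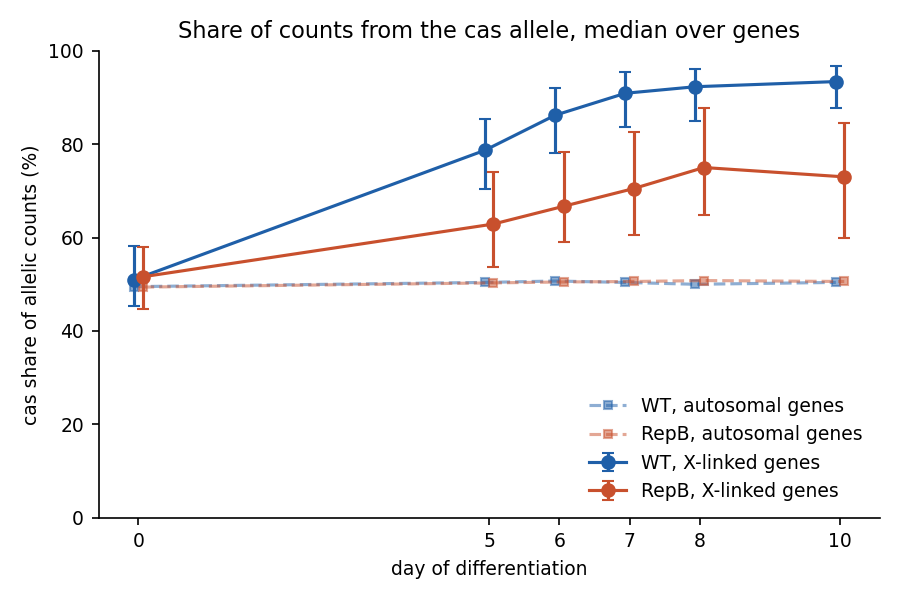
Median cas share in percent over informative X-linked genes and over autosomal background genes, by day, for WT and RepB, with 1 library per point and bars from the lower to the upper quartile of X-linked genes. The X-linked medians started at 51.0% and 51.6% and reached 93.4% in WT and 73.0% in RepB at day 10, while the autosomal medians stayed between 49.4% and 50.8%.

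Gene by gene, the lower cas share in RepB was spread over most of the X chromosome. Of 331 informative X-linked genes, 196 had a lower cas share in RepB over days 5 to 10, 1 had a higher share (Xist) and 134 were not called. Of 3203 autosomal genes, 6 were lower and 15 higher. Flna, which encodes an actin crosslinker (X chromosome, mm9, first listed exon 71468800 to 71469316), had a cas share of 94.3% ± 2.68 in WT and 63.2% ± 2.15 in RepB (SD, n = 5 days; log2 odds ratio -3.31 ± 0.13 SE, adjusted p = 1.55e-14). Its shares at day 0 were 47.6% and 46.1%. Tspan7 (94.7% and 65.6%), Foxo4 (94.4% and 69%), Haus7 (91.3% and 56.6%), Plxna3 (92.1% and 56.1%), Fam3a (89.7% and 56.4%) and Ccdc22 (89.3% and 53.1%) were among the next by size of the odds ratio. In each pair the WT mean comes first, and all 6 genes passed the allele test. In RepB, Ccdc22 had stood at 53.6% at day 0. At day 0, 0 of 331 X-linked genes and 0 of 3203 autosomal genes passed the edgeR allele test, and 4 and 100 had an unadjusted p under 0.05; no other tool was run on allelic counts.

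Both lines gained cas share with differentiation. The share rose from day 0 to days 5 to 10 for 271 of the 331 X-linked genes in WT and for 132 in RepB, and it fell for 0 in each by the edgeR test (unadjusted p under 0.05 in either direction for 299 and 211). The difference between the lines was itself greater over days 5 to 10 than at day 0 for 97 genes, all with a lower cas share in RepB (69 to 123 with 1 day left out). Day 0 is 1 library per genotype, which the fit matches exactly, so the spread behind these counts from day 0 comes from days 5 to 10 alone. Among 223 genes with a cas share of 25% to 75% at day 0 in both lines and enough counts on each of the 5 later days, 201 had a mean of at least 75% over days 5 to 10 in WT and 72 in RepB.

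Among genes known to escape X-inactivation, which stay active on the silenced X, several had a lower cas share in RepB than in WT. Ddx3x, an RNA helicase, had cas shares of 72.6% ± 3.53 in WT and 57.5% ± 3.6 in RepB (adjusted p = 1.03e-06). Kdm5c, a histone demethylase, had 77.5% ± 3.68 and 61.4% ± 4.5 (adjusted p = 3.18e-07), and Utp14a had 72% ± 6.88 and 48.7% ± 6.22 (adjusted p = 3.81e-09). Kdm6a, with 66.6% and 55.6% (adjusted p = 0.159), Firre, with 55.4% and 47.1% (0.156), and Pbdc1, with 83.5% and 83.2% (0.978), did not pass. Among genes tied to the presence of an X pair in ES cells, Tfe3 had 87.9% and 62%, Amot 96.9% and 84.2%, Klhl13 85.3% and 77.4% and Dusp9 82.3% and 66.6%, all past the threshold. Nr0b1, with 65.2% and 71.8% (adjusted p = 0.327), did not pass. Rlim, an activator of Xist, had 89.7% and 80.8% (adjusted p = 0.00862). The call of a gene depends on its allelic depth, and RepB libraries held fewer X-linked allelic counts (24028 to 49133 over days 5 to 10) than WT libraries (41683 to 110823).

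**Figure D3:**
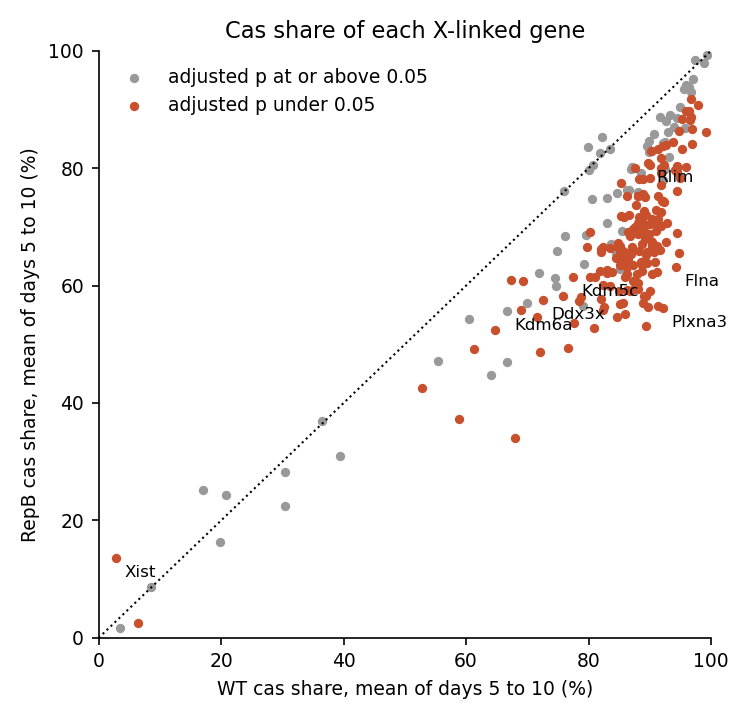
Mean cas share in percent over days 5 to 10 for each of 244 X-linked genes, WT on the horizontal axis and RepB on the vertical axis, with genes past the allele test threshold coloured. Below the diagonal of equal shares lie 233 genes, and 174 passed the test.

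Total expression from the X chromosome was higher in RepB than in WT over days 5 to 10. The X-linked median log2 RepB/WT less the autosomal median was 0.185, 0.218, 0.211, 0.251 and 0.237 at days 5, 6, 7, 8 and 10, and -0.063 at day 0. The mean over the 5 days was 0.22 ± 0.025 (SD, n = 5), a 1.16-fold difference, above 0 on 5 of 5 days (exact two-sided sign-flip p = 0.0625, the smallest possible). It was measured over 515 X-linked and 13266 autosomal genes, of which 70.1% and 46.7% were higher in RepB. No median of 10000 expression-matched autosomal lists reached that of the X (0 lists, highest 0.018). By chromosome, the median log2 RepB/WT was 0.206 for the X and ranged from -0.048 (chromosome 15) to 0.02 (chromosome 18) for the 19 autosomes. The random lists drew genes singly from all autosomes and so leave out shifts of a whole chromosome. Chromosome 18 also lay above the highest of them.

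Relative to autosomes, X-linked expression was lower over days 5 to 10 than at day 0 in both lines, with a log2 of -0.503 ± 0.067 in WT and -0.232 ± 0.055 in RepB (SD over 5 days that share 1 day 0 library per line). The change from day 0 differed between the lines by 0.283 ± 0.025 (exact sign-flip p = 0.0625). The 5 values share 1 pair of day 0 libraries and are not independent. Neither the SD nor the p holds any spread of day 0. Split by allele, mus X-linked counts were higher in RepB by a median log2 of 0.97 ± 0.21, 1.96-fold, on 5 of 5 days, and by 1.31 ± 0.29 when summed over genes. The cas counts had a median log2 of -0.09 ± 0.05, above 0 on 0 of 5 days (exact p = 0.0625 for each allele). Summed over genes, cas counts had a log2 of -0.06 ± 0.10, above 0 on 1 of 5 days (exact p = 0.375).

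**Figure D4:**
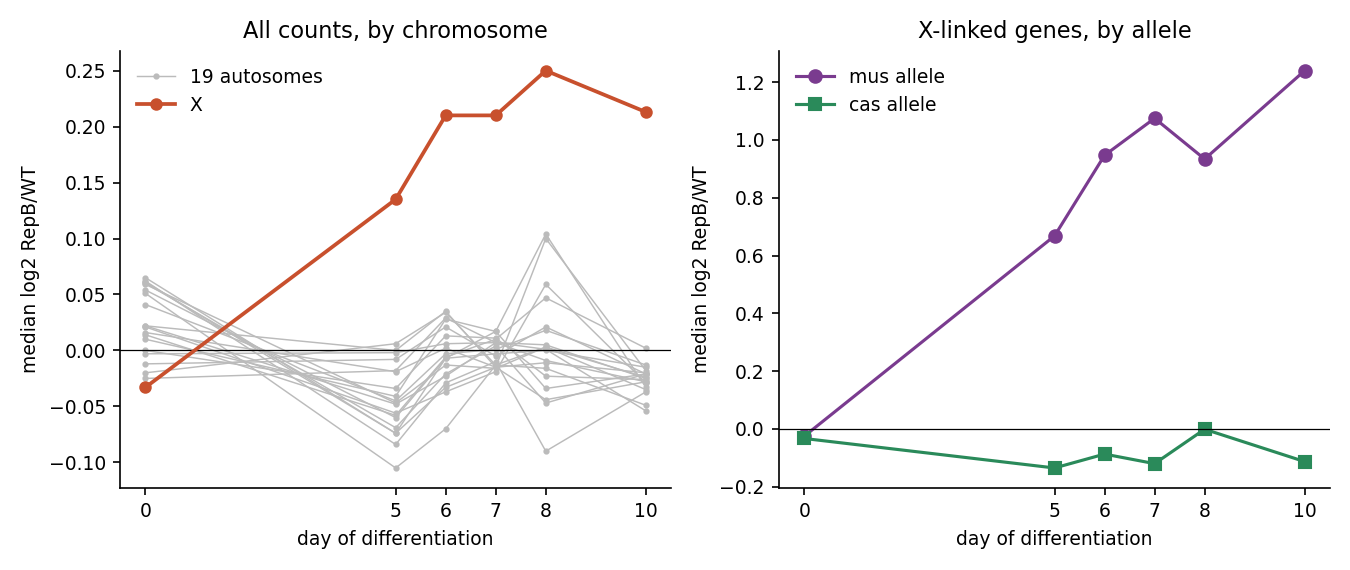
Median log2 RepB/WT by day, on the left for each chromosome from all counts and on the right for X-linked genes from mus and from cas counts. Over days 5 to 10 the mus median averaged 0.97 and the cas median -0.09, and over the same days the X stood at 0.206 in the median of gene means against -0.048 to 0.02 for the autosomes.

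Beyond the X, RepB cells had more RNA of naive pluripotency genes and less of early neural genes over days 5 to 10. Zfp42, a marker of naive ES cells, stood at 69.2 CPM in WT and 127 CPM in RepB (log2 0.90 ± 0.09 SE, adjusted p = 0.0016). At day 0 the log2 RepB/WT of Zfp42 was already 0.48. Sox1, an early neural transcription factor, stood at 10.7 and 1.38 CPM (log2 -2.68 ± 0.38, adjusted p = 0.00562). Its RepB mean lay near the detection floor, which reached 0.835 CPM in the RepB libraries, so the size of the fall is uncertain. By edgeR, 346 of 15179 genes differed, 229 higher and 117 lower in RepB, and 2271 had an unadjusted p under 0.05. The X held 82 of the higher genes, 14.6% of its 563 genes tested, and 4 of the lower. The autosomes held 147 higher genes, 1.01% of the 14615 tested, and 113 lower genes. Of the 147, 124 also fell from day 0 with differentiation, and of the 113, 52 rose and 27 fell. The count was 216, 81, 38, 744 and 134 without day 5, 6, 7, 8 or 10, with 50, 17, 6, 115 and 18 higher X-linked genes in place of 82, and 33 genes were called in all of these fits, with 0 changes of sign. It was 0 with no day term in edgeR (so that differences between days counted as spread), 50 with 1 genotype effect over all 6 days, and 592 without the low-count filter.

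Among called genes with an average log2 CPM of at least 2, a named symbol and the same sign on all 5 days, the largest rises were Mos, a kinase of the oocyte (log2 1.25 ± 0.27, adjusted p = 0.0364; already 0.82 higher at day 0), Sohlh2, a germ-cell transcription factor (1.22 ± 0.17, 0.00562; 8.98 CPM in WT and 20.1 in RepB), Hormad1, a meiotic chromosome axis protein (1.20 ± 0.21, 0.0138), Dazl, a germ-cell RNA-binding protein (1.15 ± 0.26, 0.0406), Foxr1 (1.20), Dpp4 (1.20), X-linked Usp26 (1.19) and Dppa5a (1.17; 85.3 and 160 CPM). Under the same conditions, the largest falls were Sox1, Pax6 (log2 -1.83 ± 0.38, adjusted p = 0.0284), H2-Bl (-1.58, uncertain because related genes share its sequence), Thbs2 (-1.49, near the detection floor in RepB at 0.91 CPM), Grip2 (-1.40), Miat (-1.36), Ncan (-1.32) and Ptprz1 (-1.29). Grip2 already had a log2 RepB/WT of -0.51 at day 0. Sohlh2 was called whichever day was left out. Leaving out day 7 ended the calls of the other genes of this paragraph, thinning to equal depth ended those of Mos, Dazl and Thbs2, DESeq2 those of Dazl, Grip2 and Thbs2, and limma-voom those of Pax6 and Thbs2.

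Of 21 naive pluripotency genes, 14 rose in RepB and 0 fell (17 and 0 adjusted over the list alone), with a median log2 of 0.68 (camera adjusted p = 2.78e-34, and adjusted p = 0.00485 with an estimated correlation). Klf2 (log2 0.73 ± 0.08, adjusted p = 0.0019), Esrrb (0.83 ± 0.12, 0.00562; 74 and 118 CPM) and Nanog (0.56 ± 0.08, 0.00624; 173 and 246 CPM) rose. Pou5f1 (0.33, 0.128), Sox2 (0.32, 0.0826) and Tdgf1 (0.19, 0.479) did not pass. Of 13 neural ectoderm genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone), with a median of -1.12 (adjusted p = 0.022 with an estimated correlation). Besides Sox1 and Pax6 these were Lhx2 (6.24 CPM in WT and 1.55 in RepB), Map2 (11 and 7.08) and Pax3 (1.88 and 0.176, the latter below the floor). Nes (log2 0.00, adjusted p = 1) and Tubb3 (0.16, 0.646), the most abundant neural list members, did not pass. Map2 already had a log2 RepB/WT of -0.36 at day 0. The neural count was 3 by DESeq2 (median -0.64) and 3 by limma-voom (-0.63). The naive count was 4 and the neural count 0 without day 7, and they were 5 and 2 without day 6. Without day 10 they were 9 and 1, and the call of Nanog also ended without day 7. Map2 lost its call without day 5, 6, 7 or 10, by DESeq2 and after thinning, and Pax3 whichever day was left out and by limma-voom.

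X-linked genes as a whole, the X pair list and the escape list were higher in RepB. Of 563 X-linked genes tested, 82 rose and 4 fell (162 and 16 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00485 with an estimated correlation), and 50, 17, 6, 115 and 18 rose without day 5, 6, 7, 8 or 10. Of 6 genes tied to the X pair in ES cells, 4 rose, 4 also when adjusted over the list alone (median 0.48, adjusted p = 0.022 with an estimated correlation). These 4 were Klhl13 (log2 0.58 ± 0.10), Tfe3 (0.47 ± 0.08), Dusp9 (0.50 ± 0.11) and Nr0b1 (0.60 ± 0.12, already 0.46 higher at day 0). Of 14 escape genes, 3 rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation). They were 1810030O07Rik (1.13 ± 0.14, 17 and 36.9 CPM), Usp9x (0.71 ± 0.13) and Utp14a (0.61 ± 0.10), while Ddx3x (0.31, adjusted p = 0.0654) and Kdm5c (0.16, 0.467) did not pass. In the X-inactivation centre list of 10 genes, 0 rose and 2 fell, 0 and 2 also over the list alone, Tsix among them (adjusted p of the list = 0.318 with an estimated correlation). Utp14a already had a log2 RepB/WT of 0.31 at day 0. Without day 7 the X pair count was 0 and the escape count 1, and without day 6 or 10 the X pair count was 1. Without day 8 the escape count was 6 higher and 2 lower, and it was 6 with no low-count filter and 5 by DESeq2.

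**Figure D5:**
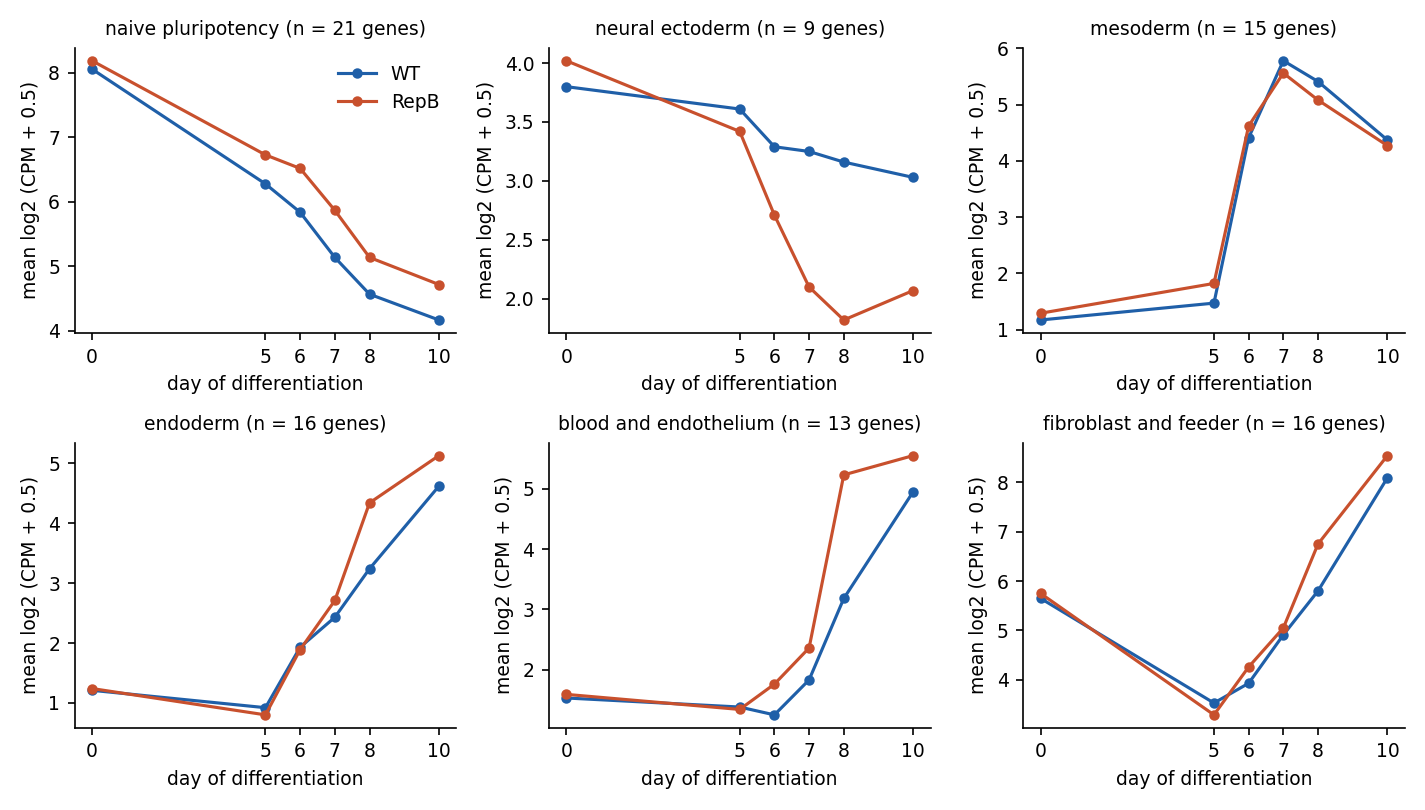
Mean log2 CPM (pseudocount 0.5) of 6 fixed gene lists by day, for WT and RepB, with 1 library per point and the number of genes averaged in each title. The naive pluripotency list fell from 8.06 at day 0 to 4.17 at day 10 in WT and from 8.19 to 4.72 in RepB.

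The other lineage lists gave smaller counts, and none of them passed camera with an estimated correlation. Of the fixed lists, besides the X-linked genes as a whole, 14 passed with the preset correlation and 4 with an estimated one, namely the naive, neural, X pair and escape lists. The X pair and escape lists hold X-linked genes and were set against all other genes, so they are not separate from the shift of the whole X. Their medians were 0.48 and 0.29, against 0.22 for X-linked genes as a whole. Of 17 endoderm genes, 3 rose (5 over the list alone), namely Ttr (log2 0.97), Apoa1 (1.51) and Apob (1.76), which encode carrier and lipid-transport proteins (adjusted p = 0.318 with an estimated correlation). Of 13 blood and endothelium genes, 3 rose (10 over the list alone): Gata2 (0.62), Pecam1 (0.82) and the globin Hbb-y (2.02, uncertain because globins share sequence; adjusted p = 0.196 with an estimated correlation). Of 13 cardiac muscle genes, Myh7 (-1.10) and Myl3 (-0.83, and already -0.89 at day 0) fell. This was a count of 2 (3 over the list alone, adjusted p = 0.344 with an estimated correlation). Of 16 fibroblast and feeder genes, Col3a1 (1.04) and Postn (1.35) rose, a count of 2 (5 over the list alone; adjusted p = 0.318 with an estimated correlation). Of 12 formative epiblast genes, 1 rose (Lefty1, 0.48) and 1 fell (Sox3, -1.11; 2 and 4 over the list alone; adjusted p = 0.318 with an estimated correlation). Of 8 trophoblast genes, 1 rose (Tfap2c, 0.62; 1 over the list alone; adjusted p = 0.225 with an estimated correlation).

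Of 21 imprinted genes, H19 (log2 0.51) and Usp29 (0.45) rose, a count of 2 (4 over the list alone; adjusted p = 0.253 with an estimated correlation). Of 12 p53 targets, X-linked Eda2r rose (0.51), and 2 did over the list alone (adjusted p = 0.318 with an estimated correlation). Of 18 Xist partners, X-linked Atrx rose (0.48), 1 also over the list alone (adjusted p = 0.921 with an estimated correlation). Of 16 mesoderm genes, 30 Polycomb subunits, 34 Hox genes, 81 ribosomal protein genes and 16 cell cycle genes, 0 passed the edgeR test in either direction, and 0 over the list alone. Without day 8, 1 Polycomb subunit was higher and 2 were lower, and 3 ribosomal genes were higher. Without day 10, 1 mesoderm gene was higher, and without day 5 or 6, or after thinning, 1 ribosomal gene was lower. With no low-count filter 1 Hox gene and 1 ribosomal gene were higher and 6 ribosomal genes were lower. Their adjusted p values with an estimated correlation were 0.677, 0.423, 0.255, 0.677 and 0.677. Leaving out day 7 ended every call named among the lineage, imprinted, p53 and Xist partner genes except those of Hbb-y and Sox3, and leaving out day 10 ended that of Hbb-y. Day 8, whose libraries correlated least, carried part of these values. Without it the median fell from 1.04 to 0.6 for the blood list, from 0.73 to 0.35 for the endoderm list and from 0.39 to 0.26 for the fibroblast list, Col3a1 stood at 0.61, and Postn (0.55) and Ttr (0.76) were not called (adjusted p = 0.0578 each). The genes called in these lists were then 4, 2 and 3. The blood count was 9 with no low-count filter, 5 by limma-voom or after thinning, 1 without day 7 or with 1 genotype effect over all 6 days, and 0 with no day term. The fibroblast count was 4 with no low-count filter. DESeq2 ended the calls of Apob, Hbb-y, Myl3, Col3a1 and Postn, limma-voom that of Postn, and thinning those of Apoa1 and Myl3. Y-linked genes were too few to test, and Ddx3y stood at 1.79 and 1.49 CPM at day 0 and at 0 and 0.028 CPM later.

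At day 0 the WT library had more Xist and less Tsix than the RepB library, and over days 5 to 10 Tsix was lower in RepB. In the test of RepB against WT over days 5 to 10 less that at day 0, Xist rose in RepB relative to WT (log2 2.08 ± 0.28, adjusted p = 0.0303) and Tsix fell (-1.59 ± 0.23, 0.0436). Myc, a proliferation regulator, also fell (-1.66 ± 0.22, 0.0303). It stood at 15.2 CPM in WT and 41.5 in RepB at day 0, and at 117 and 98.4 CPM later. By edgeR 5 genes passed of 15179, and 1345 had an unadjusted p under 0.05. The other members were the predicted genes Gm5148 and Gm5088, named because the count is small. They were seen at 17.3 and 28 CPM in the WT day 0 library and at 0.0648 and 0.194 CPM in the RepB day 0 library. Jpx, Ftx and Rlim did not pass, with adjusted p of 0.349, 0.678 and 0.351. The naive pluripotency list (median log2 0.64) and the X-linked genes (0.27) were higher in this test, each with adjusted p = 0.0353 with an estimated correlation. The neural list (median -1.33) had adjusted p = 0.11. The count was 0 without day 5, 7 or 10 and 61 without day 8, and it was 14 without the low-count filter, 12 by DESeq2 and 28 by limma-voom. The call of Tsix also ended without day 6, with size factors by relative log expression and after thinning. The day 0 side rests on 1 library per genotype, which the fit matches exactly, so the spread in this test comes from days 5 to 10 alone.

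Most genes differed between days 5 to 10 and day 0, in a test that averaged over the lines. Day 0 cultures also differed by feeders and LIF, and 5 of 16 fibroblast and feeder genes fell while 4 rose. By edgeR 9724 of 15179 genes differed between days 5 to 10 and day 0, 4819 higher and 4905 lower. Of the 21 naive pluripotency genes, 20 fell, 20 also over the list alone (median log2 -2.49, adjusted p = 0.0157 with an estimated correlation), including Esrrb (-3.72 ± 0.11), Klf2 (-3.49 ± 0.08) and Nanog (-2.25 ± 0.08). The immediate early genes Fosb (-7.92), Egr1 (-5.92), Egr2 (-5.51) and Fos (-5.48) fell. Inhbb, Mgp, Slc13a5 and Halr1 were the other large falls. Of 16 mesoderm genes, 12 rose, 12 also over the list alone, including Hand1 (5.26 ± 0.28) and T (6.06 ± 0.65; adjusted p of the list = 0.234 with an estimated correlation). The epithelial keratins Krt8 and Krt18 rose by 5.50 ± 0.19 and 5.52 ± 0.23. The named genes with the largest rises were near or below the detection floor at day 0. Hba-x and Hbb-bh1, embryonic globins, had 0 counts at day 0 in both lines and means of 53.1 and 34.6 CPM later in WT, uncertain because globins share sequence. Prdm6, Aplnr, Gbp2b, Fgf5 and X-linked Cysltr1 also rose, to WT means of 115, 43.2, 64.6, 121 and 6.92 CPM. Of 563 X-linked genes, 272 fell and 120 rose, 275 and 121 adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). Without day terms the count was 3871, and the calls of Nanog, Hand1, T, Hba-x and Hbb-bh1 ended.

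Over days 5 to 10, 13 of 14 fibroblast and feeder genes rose and 1 fell, 13 and 1 also adjusted over the list alone (adjusted p = 0.0902 with an estimated correlation). Of 12 formative epiblast genes 9 fell and 0 rose by edgeR, 9 and 0 also over the list alone (adjusted p = 0.0995 with an estimated correlation). The slope per day was positive for Postn (log2 2.88 ± 0.22 per day), Col3a1 (2.01 ± 0.19), Pitx1 (1.95), Col1a2 (1.89), Ttr (1.88), Hand2 (1.86), Hand1 (1.85) and Snai2 (1.83). It was negative for Slc27a2 (-1.68 ± 0.07), T (-1.54), Wnt8a (-1.48), Nefl (-1.32), Foxi3 (-1.27), Pim2 (-1.26), Fgf5 (-1.23) and Tmem154 (-1.23). By edgeR 7056 of 12948 genes had a slope, 3615 up and 3441 down. The call of T ended without day 6, 8 or 10 or with limma-voom, and that of Hand1 without day 5 or 6. Of 21 imprinted genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 0.0306 with an estimated correlation).

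No gene passed the test for a different slope in RepB and WT. By edgeR the count was 0 of 12948, with 200 genes at an unadjusted p under 0.05, and it was 0 by DESeq2 and by limma-voom. The genes with the smallest p, none past the threshold, were Cotl1 (log2 0.23 ± 0.05 per day), Irs4, Adamts19, Mir703 and Tgm2, each with adjusted p = 1. Xist had a slope difference of 0.08 ± 0.09, with adjusted p = 1. Tsix, Jpx, Ftx and Rlim had -0.01, -0.01, 0.02 and 0.00. On simulated data this test called 1 of 67 genes whose difference reached 2-fold between days 5 and 10, so moderate differences in slope were not detectable. The fit had no term for single days, so a curved course shared by the lines counted as spread. Fewer genes had an unadjusted p under 0.05 than chance alone would give, so the lack of calls is not evidence of equal slopes. The simulation used flat courses and does not include this loss.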

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

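The tests of slower differentiation, of silencing of the other X, of feeder RNA at later days and of both explanations for Xist at day 0 were chosen only after the results were seen, while the splits of the libraries and the test of undifferentiated cells were set before.

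X-linked genes had a lower cas share in RepB than in WT over days 5 to 10, for 196 of 331 genes by the edgeR test. The difference less that at day 0 passed for 97, but with 1 library per genotype at day 0 the spread of that test comes from the later days alone. Slower differentiation of the RepB line stays open, since the test by matched days cannot decide it. Every WT median share over days 5 to 10 lay above every RepB one, so any match among these days gives a negative difference. WT days before day 5 could not be matched. At the WT day with the most similar autosomal expression, the cas share difference was -18.9 points ± 1.7 (SD over 5 days). On the same day it was -18.7 ± 2.1, so matching within days 5 to 10 did not lessen it. Silencing of the cas X in part of the cells as the whole cause would leave total X-linked output equal, but it was higher in RepB by a log2 of 0.22 ± 0.025. RNA from feeder cells would shift autosomal genes as well, and these differed by 0.18 points ± 0.37. Incomplete silencing of the mus X in RepB may account for the rest, as a hypothesis that arose from these data and was not itself tested. A smaller part from silencing of the cas X stays open, since Xist reads were 6.4% to 18.6% cas in RepB. By pooled counts, a cell share of 22.6% to 33.7% would be needed to give all of the lower cas share if each cell silenced 1 X. The Xist cas share lay below the share needed on each day, at 18.6% against 33.7% on day 5. On day 10 it was 6.4% against 26.8%. Xist reads do not count cells, however.

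The naive pluripotency list had a higher RepB/WT ratio over days 5 to 10 than at day 0, by a median log2 of 0.64. Slower differentiation shared by autosomal genes as a whole is argued against within days 5 to 10. At the matched WT day the list mean log2 ratio was still 0.65 ± 0.13, against 0.60 ± 0.11 on the same day. WT days before day 5 could not be matched, so an earlier state was not examined. A larger share of undifferentiated cells in RepB would raise other genes that fell at least 8-fold in WT, and the median log2 ratio of 565 such autosomal genes was 0.19 ± 0.10. That value lies between the bounds set for the presence and the absence of such cells, so this explanation cannot be told apart from a change within cells. The genes were chosen by their fall in the same WT libraries that enter the ratio, a choice that by itself tends to raise it. A direct effect of the genotype, or of X-linked gene dose, was not tested and stays open.

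The RepB/WT ratios of Xist and Tsix over days 5 to 10 less those at day 0 were 2.08 and -1.59 on the log2 scale, but day 0 had 1 library per genotype, the spread came from the later days alone, and no call of this test was left without day 5, 7 or 10. Feeder RNA in the WT day 0 library is argued against for Xist, since 16 fibroblast and feeder genes had a median log2 WT/RepB of -0.17 ± 0.30 (SD over genes) at day 0 against 1.79 for Xist in size. Differentiated cells in the WT day 0 culture would raise its X-linked cas share, which differed by -0.7 points (WT less RepB). A difference between these cultures or lines at day 0 stays open, with 1 library each, and the strand setting of the counting leaves Tsix uncertain.

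Other genes whose RepB/WT ratio differed between day 0 and later were Myc, with an interaction log2 of -1.66, Gm5088, with 7.75, and Gm5148, with 8.77. The last 2 values depend on the prior count, since both genes were near the floor outside the WT day 0 library. The X-linked genes as a list had a median interaction log2 of 0.27.

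Single days lay apart from the other days of their gene in 6 of 69 series of 5 days tested, where chance gives about 3.5. The log2 RepB/WT of Kdm5c was 0.53 at day 8 against -0.01 to 0.14 on the other days. That of Pou5f1 was 0.83 at day 10 against 0.09 to 0.27. Prdm14 stood at -0.33 at day 10 against 0.75 to 1.09, and Sox3 at -0.22 at day 10 against -1.34 to -1.17. Myl3 stood at -0.96 at day 8 against -0.75 to -0.71, and H19 at -0.08 at day 5 against 0.57 to 0.72.

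Among 80 splits of the 10 libraries of days 5 to 10 into 5 and 5, only the real one (1 split) gave as many as 346 genes, and the highest other count was 72. The same held for the 5 genes of the interaction (1 split, highest other 2) and for the 196 X-linked genes with a lower cas share (1 split, highest other 69), a share under 0.05 of these splits. The days pair the libraries, however, and most of these splits put both libraries of some days in 1 group. Only 16 splits part the libraries of every day, too few for a share under 0.05, and among them the highest other counts were 1, 0 and 2 against 346, 5 and 196. For the difference of slopes the real split gave 0 genes, which all 80 splits must reach, so this count tests nothing; the highest other split gave 953.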

How the results depend on the processing

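Thinning the deeper library of each day and limiting the allelic share to genes with both alleles at day 0 were chosen only after seeing the data, as were all settings for the 97 X-linked genes whose cas share difference between the lines was greater over days 5 to 10 than at day 0 (69 to 123 with 1 day left out, 108 after thinning). The ribosomal list, lower at the preset correlation, changed the sign of its median without day 8 (-0.09 to 0.02). The count of 346 genes between RepB and WT became 592 with no low-count filter, 50 with 1 genotype effect over all 6 days and 0 with no day term, that is without the replicate block by day. It was 38 to 744 with 1 day left out, lowest without day 7 and highest without day 8, and 317 after thinning. The 5 genes of the interaction became 14 without the filter, 12 with DESeq2, 28 with limma-voom and 0 to 61 with 1 day left out. The 9724 genes changed from day 0 became 3871 with 4 groups and no day terms. The X-linked output difference was 0.18 as a mean over genes. Its change from day 0 was 0.32 at a mean CPM of at least 10, 0.22 as a mean over genes and 0.24 with no autosomal reference. The cas share difference was -15.3 points with pooled counts, -19.4 to -18.2 with 1 day left out and -19.3 after thinning. Lists passing camera fell from 14 to 4 with an estimated correlation. Counts without day terms fell because differences between days then count as spread, and for the other settings the cause was not tested. The 7056 genes with a slope, the 0 with a different slope, the 196 X-linked genes with a lower cas share (168 to 196 with 1 day left out, 174 after thinning) and the Xist ratio stayed within 1.5 times or 1 SD of their values. For named genes between RepB and WT, 590 results kept their side of the threshold, 230 lost it, 16 gained it and 8, of Xist, Amot, Jpx and Nes, were not called and changed sign or moved. Depth limits the RepB libraries most, where 3 counts were up to 0.835 CPM.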

Other observations

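The tests named here were set before their results were seen, except for the choice of Col12a1, Itga11 and Cd109, which was made only after their values were seen.

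The cas share of allelic counts differed between chromosomes. At day 0, pooled over the lines, it was 47.0% on chromosome 9, 47.8% on chromosome 13 and 49.9% on the X. It was 40% on chromosome 5, 39.7% on chromosome 7 and 34.2% on chromosome 8. It was 23.8% on chromosome 11, 22.8% on chromosome 2, 12.9% on chromosome 6 and 2.0% to 8.9% on the remaining autosomes. The mean log2 CPM of the fibroblast and feeder list, whose members did not all move alike, was 5.65 in WT and 5.75 in RepB at day 0, 3.53 and 3.29 at day 5, and 8.09 and 8.54 at day 10.

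Bgn, an X-linked matrix proteoglycan made by fibroblasts, was almost wholly of the mus allele at day 0, with a cas share of 0.6% over both lines, and had 83.2% over days 5 to 10. It fell from 244 CPM at day 0 to 3.0 CPM at day 5 in WT. RNA from feeder cells in the day 0 libraries may account for this, as a hypothesis. It predicts a lower day 0 cas share for other fibroblast genes on chromosomes 9, 13 and X, and the median difference was -30.0 points over 2 genes, Thy1 (49.4% and 63.0%) and Tagln (1.5% and 48.0%). With so few genes, which differ from each other, feeder RNA cannot be told apart from other sources. Col12a1 (0.2% and 63.5%), Itga11 (0.9% and 66.2%) and Cd109 (4.7% and 63.9%), matrix and surface genes of chromosome 9, had the same direction. They were picked for a day 0 share far below the later one, so this direction was fixed by the choice and adds no support.

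Genes farther from Xist might have had a larger RepB deficit in cas share. The median deficit was 12.2 points over 42 genes within 10 Mb and 21.7 points over 60 genes beyond 60 Mb. Across 223 genes the Pearson r was 0.26 and Spearman's rho 0.22 (permutation p = 8e-05 and 0.00086, adjusted 0.0002 and 0.0014 over 5 relations), but genes are not independent and neighbours are alike. Circular shifts along the chromosome, which keep neighbours together, gave a permutation p of 0.56 for all genes, and for the 181 genes beyond 10 Mb r was 0.21 with p = 0.4. A relation with distance therefore cannot be told apart from the arrangement of neighbouring genes.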
